A study of Mus musculus with 2 samples.

How the data were processed

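Messenger RNA was measured in mouse small-intestinal organoids, which are cultures of gut epithelium grown in a gel matrix from isolated crypts. The organoids came from reporter mice in which green fluorescent protein (GFP) is produced under control of the chromogranin A gene. Per the labels' protocols, dissociated epithelial cells were sorted by fluorescence, about 1% of them were GFP+, and the remaining GFP- cells were kept for comparison. Polyadenylated RNA from each fraction was amplified with a low-input cDNA kit and sequenced. The series used here holds 2 libraries, 1 per fraction.

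The deposited values are FPKM (fragments per kilobase of transcript, scaled to the size of the library), per the file headers. FastQC, TopHat2 0.7, Cufflinks and Cuffdiff on the mm10 mouse genome are named in the submitters' processing notes. The gene annotation, the library scaling and the handling of reads that map to several places are not given in the sources used here. Each file lists 23793 gene rows with an FPKM, a lower and an upper confidence bound and a status. Of these, 333 rows join several symbols, 161 symbols occupy more than one row (417 rows), and 26 symbols have been turned into dates, as spreadsheet programs do. The locus field of 4628 rows is shared with another row and covers a merged region, so it is not the position of a single gene. Locus starts were counted from 0 in the files and were shifted to count from 1. Listed loci can differ from the annotated gene: that of *Slc18a1* runs past it and that of *Cacna1a* starts inside it (GENCODE M21).

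In the GFP+ library, 5 rows carry the status HIDATA, by which Cuffdiff marks loci with too many fragments to be estimated. They are listed at 0 with both bounds at 0, and were treated as not estimated rather than as 0. The GFP- library has no such row. Rows with the status FAIL (11 in either library) have a value and were kept. The lower bound is 0 for every row of the GFP+ library and for all but 1 row of the GFP- library, and among rows of at least 1 FPKM the upper bound is a median of 2.35 times the FPKM in each.

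FPKM values are not counts, and the files give no depth, but the low values of the deposited FPKM appear to come in steps. Single-transcript genes longer than 3000 bases were used (lengths from GENCODE M21, built on the same mouse assembly). Their most populated low step was taken as 1 fragment. It corresponded to 59.0 fragments per FPKM and kilobase in the GFP- library (40 genes in the step, within 5%) and to 59.8 in the GFP+ library (18 genes). Of the values below 4.5 such fragments, 75.2% of 109 genes in the GFP- library and 59.0% of 83 genes in the GFP+ library lay within 0.1 of a whole number. Evenly spread values would give 20% for a unit chosen without the data. Here the unit was chosen from the same values, so the share is no independent check. On this scale 1 FPKM of a 3 kb transcript stands for about 177 fragments in the GFP- library and 179 in the GFP+ library, and a transcript of 2 kb listed at 0 has a limit of about 0.0254 FPKM (3 fragments) in the GFP- library and 0.0251 in the GFP+ library. These figures cover counting error only. Amplified fragments without molecular identifiers are not independent molecules.

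FPKM was summed per symbol, which left 23532 symbols estimated in both libraries. The 11868 symbols of at least 1 FPKM in the higher library were compared by log2((FPKM + 1) in GFP+ / (FPKM + 1) in GFP-). This scale understates the change of genes with low values, so FPKM values are given beside it. With 1 library per fraction no test between fractions is possible. Genes were set apart by a rule of size, a difference of at least 2 on the log2 scale (4-fold). For each of 31 gene lists, the median difference over members of at least 1 FPKM was placed among 10000 random lists of the same size matched on mean log2(FPKM + 1) in 20 bins. This percentile describes these 2 libraries, and genes are not replicates. A member below 1 FPKM in one library passes the filter only through the other, which fixes the sign of its difference. This concerns many members of the exocytosis, synaptic adhesion, channel and non-epithelial lists. A list member was also accepted where its symbol was part of a joined row. Lists given by a prefix take in some other proteins: the ribosomal list holds kinases named Rps6k and the serotonin receptor list holds proteases named Htra. The intervals given for list medians are distribution-free 95% intervals over genes, or the range with fewer than 6 members.

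The size rule, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 15 genes with the largest and the 15 with the smallest difference among those of at least 10 FPKM in the higher library and status OK in both, up to 4 members of each list with the largest absolute difference, members whose value goes against their list, and 11 genes of the serotonin and chemosensory system. Of the members that go against their list, only those past the 4-fold rule were taken, a narrowing chosen when the rule was applied. Other genes that are named were chosen after their values were seen: *Chgb*, *Reg4*, *Afp*, *Cck*, *Gip*, *Pyy*, *Nts*, *Spr*, *Pts*, *Qdpr*, *Isl1*, *Neurog3*, *Mki67*, *Lgr5*, *Lyz1*, *Defa24*, *Lct*, *Sis*, *Muc2*, *Tff3*, *Bsn*, *Lpar5*, *Ffar4*, *Gapdh*, *Rn45s*, *Lars2*, *Mir6236* and those of the closing observations. A few genes that the rule takes are not reported here. Alternatives were another pseudocount, another filter, another scaling, single-row symbols, status OK, another threshold and another matching. The size rule was tested on simulated data in which 200 of the real genes were changed by known folds and 11466 genes passed the filter. The changed genes were drawn only from those with a mean of at least 5 FPKM over the 2 libraries. It recovered 100% of those raised 8-fold and 98% of those lowered 8-fold and called 0 unchanged genes. Recovery below 5 FPKM was not simulated. Of 200 lists drawn at random from all simulated genes, 5% lay outside the central 95% of their random lists. Random drawing sets about that share in advance, so it is no check of the percentiles of real lists. The simulation held counting error only. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.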

Results

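The transcriptome of chromogranin A reporter cells was compared with that of the other epithelial cells of the same organoid cultures, to list the genes of serotonin-producing enterochromaffin cells, the enteroendocrine cells in which chromogranin A is abundant. There was 1 GFP+ library and 1 GFP- library. Neither fraction was replicated, so no difference below has a replicate check or a p-value, and differences are described by their size in these 2 libraries. At least 1 FPKM was listed for 10599 rows in the GFP- library and for 11480 rows in the GFP+ library. Without the 5 loci that had no estimate in GFP+, the 100 most abundant genes held 25.6% of the summed FPKM in the GFP- library and 18.1% in the GFP+ library. Those loci had too many fragments to be estimated in GFP+, so the 2 shares cannot be compared as they stand. Across the 11868 genes of at least 1 FPKM in either library, the log2 levels of the 2 libraries had a Pearson r of 0.78, a correlation over genes, which are not independent replicates.

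The level of the reporter gene itself could not be compared. *Chga* (chromosome 12, 102554969 to 102565027, mm10, a protein-coding gene on the plus strand; positions here and below are the loci listed in the files) was at 133 FPKM in the GFP- library and had no estimate in the GFP+ library, where Cuffdiff stopped on too many fragments and listed it at 0. The same held for *Chgb*, the second major granin gene, at 392 FPKM in the GFP- library, and for *Reg4* at 419 FPKM and *Afp* at 39.6 FPKM. The gene of the reporter thus gave no ratio between the libraries. By its status alone, the locus passed the fragment limit in GFP+ and not in GFP-.

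In the GFP+ library 841 genes were at least 4-fold higher than in the GFP- library and 545 were at least 4-fold lower, on the log2(FPKM + 1) scale, so that 60.7% of the 1386 genes that passed the size rule were higher. The deposited confidence bounds of the 2 libraries overlapped for every row with an estimate, the lower bounds being at 0 for all but 1 row. The 5563 genes of at least 10 FPKM in both libraries had a median log2 ratio of -0.50, so that a typical well-expressed gene had a lower FPKM in GFP+. With this median set to 0, 1317 genes were higher and 184 lower (87.7% higher). With both libraries rescaled to one total, 1717 were higher and 153 lower (91.8% higher). The median difference over all genes tested was -0.12 as deposited and 0.35 and 0.50 under these scalings. With a pseudocount of 0.1 or 5 in place of 1, 1524 or 353 genes were higher and 809 or 315 lower. Differences near -0.50 are those of a typical gene of at least 10 FPKM in both libraries, not of a typical tested gene. With a pseudocount of 5, *Ada*, *Adcy1*, *Cacna2d1*, *Ccl9*, *Cntnap2*, *Dll4*, *Fos*, *Gast*, *Gper1*, *Lfng*, *Lyz2*, *Nr4a1*, *Nts*, *Pecam1*, *Penk*, *Ret*, *Rgs13*, *Slc6a4* and *Trpc4* no longer passed the rule. With a pseudocount of 0.1, *Cacna1a*, *Cacnb2*, *Cd68*, *Chrm4*, *Chrnb2*, *Chrnb4*, *Col1a1*, *Col3a1*, *Gfap*, *Hey1*, *Htr1d*, *Lrrtm2*, *Nefl*, *Nrxn2*, *Olfr561*, *Scn3b*, *Scn8a* and *Tmem63c* also passed it as higher, and *Atoh1* and *Trpm5* as lower. With one total, but not with the median ratio set to 0, *Cacnb2*, *Chrnb2*, *Col1a1*, *Col3a1*, *Lrrtm2* and *Olfr561* passed it as higher. *Cacna1a* passed it under both of these scalings.

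**Figure D1:**
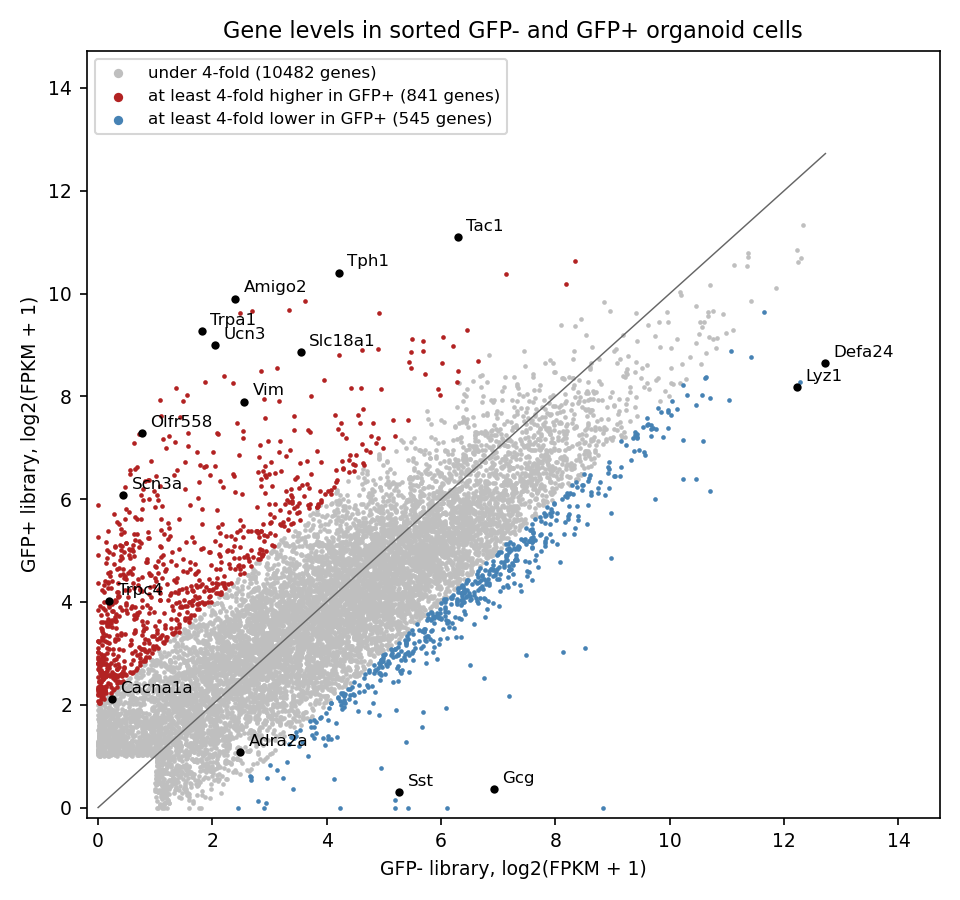
Level of each gene in the GFP- library (x axis) and the GFP+ library (y axis), both as log2(FPKM + 1), for genes of at least 1 FPKM in either library; each point is 1 gene, the line marks equal levels, and red and blue mark the 841 higher and 545 lower genes. Serotonin and sensory genes such as *Tph1* and *Trpa1* lie far above the line, and *Gcg*, *Sst* and the Paneth cell genes *Lyz1* and *Defa24* lie below it.

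Of 8 genes of serotonin synthesis and storage, 5 were at least 4-fold higher in the GFP+ library and none was 4-fold lower. *Tph1*, the rate-limiting enzyme of serotonin synthesis outside the brain (chromosome 7, 46644641 to 46672537), was at 1359 FPKM in GFP+ and 17.5 FPKM in GFP-, a ratio of 77.6, with upper bounds of 3903 and 43.3 FPKM. *Slc18a1*, a vesicular monoamine transporter (listed locus chromosome 8, 69037708 to 69113717, which runs past the annotated gene), was at 462 against 10.7 FPKM. Its relative *Slc18a2* was at 94.0 against 0.467 FPKM. *Ddc*, which converts the *Tph1* product to serotonin (chromosome 11, 11814101 to 11898144), was at 402 against 63.9 FPKM, and *Gch1*, which starts the synthesis of the cofactor of *Tph1*, was at 177 against 18.0 FPKM. The other cofactor enzymes did not pass the rule, with log2 differences of 0.81 for *Qdpr*, -0.90 for *Pts* and -1.73 for *Spr*. The list median was 2.93, above each of 10000 random lists matched on expression, with an interval from -1.73 to 6.20 over its genes.

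Of 4 genes of serotonin breakdown and uptake, 2 were at least 4-fold lower as deposited and 0 under either other scaling. *Maoa*, which degrades monoamines, was at 23.9 FPKM in GFP+ and 116 FPKM in GFP-. *Slc6a4*, the serotonin reuptake transporter, was at 9.58 against 42.2 FPKM. *Aldh2* and *Maob* had log2 differences of -1.01 and -0.13, and *Maob* was above 0 under both other scalings. The median of the 4 genes was -1.52, at the 4.52 percentile of matched random lists.

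Proteins of the dense-core granules in which peptides and amines are kept were higher as a group. Of the 14 list members with an estimate, 12 were at least 4-fold higher and none was lower, with a median log2 difference of 4.48 (interval 2.06 to 5.99), above each random list. *Resp18* was at 817 FPKM in GFP+ and 9.09 FPKM in GFP-. *Pcsk1*, a prohormone convertase, was at 930 against 11.3 FPKM, *Vgf* at 149 against 1.35 FPKM and *Ptprn* at 107 against 0.894 FPKM. The machinery of regulated exocytosis was higher too, in 20 of 24 members, with a median of 3.50 above each random list. Many of the 24 were below 1 FPKM in GFP- and passed the filter only through GFP+, which fixes the sign of their difference. Without the filter 20 of 32 members passed the rule, with a median of 2.63. At a pseudocount of 5, 13 members passed the rule with a median of 2.16, and at 0.1, 22 passed it. *Snap25*, a SNARE protein of synaptic vesicle fusion, was at 137 against 1.53 FPKM. *Cplx1* was at 104 against 1.87 FPKM, *Syt13* at 153 against 3.28 FPKM and *Rab3c* at 48.2 against 0.611 FPKM. *Bsn*, a scaffold of the presynaptic active zone, was the single member below 0, at 0.682 against 2.87 FPKM. Only 4 of 16 synaptic adhesion genes reached 1 FPKM. *Cntnap2* was at 5.38 against 0.0298 FPKM, and *Nrxn2*, *Lrrtm2* and *Homer1* had differences of 1.85, 1.22 and -0.04. Under both other scalings *Nrxn2* passed the rule and *Homer1* was above 0. Their median was 1.53, at the 96.6 percentile.

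Among the sensory receptors, *Trpa1* stood out. This ion channel for irritant chemicals (chromosome 1, 14872648 to 14918862) was at 617 FPKM in GFP+ and 2.52 FPKM in GFP-, a ratio of 245 and a log2 difference of 7.46. Of 13 TRP channel genes above 1 FPKM, 5 were at least 4-fold higher and none was lower. With a pseudocount of 5, 3 were higher, with one total 8 of 14, and with a pseudocount of 0.1 7 were higher and 1 lower. Their median of 1.44 was at the 99.9 percentile. *Trpm2* was at 51.2 against 0.206 FPKM and *Trpc7* at 46.3 against 0.251 FPKM. *Trpc4* (chromosome 3, 54156057 to 54318471) was at 15.3 against 0.144 FPKM. The odorant receptor *Olfr558* (chromosome 7, 102702323 to 102712054) was at 155 against 0.704 FPKM. A joined row of its neighbours *Olfr560* and *Olfr78*, which the counting did not separate, was at 74.4 against 0.380 FPKM. Of 1111 odorant receptor symbols in the files, 5 reached 1 FPKM and these 2 rows passed the rule as deposited (3 with one total), with *Olfr561* and *Olfr165* at 1.30 and 1.02 FPKM in GFP+.

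Of 8 receptors for nutrients and metabolites above 1 FPKM, 4 were at least 4-fold higher, with a median of 1.63 at the 99.9 percentile. Of these 4, *Olfr558* and the joined row of *Olfr560* and *Olfr78* are the odorant receptors already described. Without them the median of the other 6 was 1.07, at the 93.5 percentile, inside the central 95% of random lists. *Ffar2*, a receptor for short-chain fatty acids, was at 74.2 FPKM in GFP+ and 3.56 FPKM in GFP-, and *Gper1* at 6.22 against 0.764 FPKM. *Lpar5* and *Ffar4* had -0.93 and -0.36, the latter above 0 under both other scalings. None of the 35 bitter taste receptor symbols reached 1 FPKM in either library. Among the adrenergic receptors, *Adra2a* (chromosome 19, 54045182 to 54048982) was at 1.10 FPKM in GFP+ and 4.61 FPKM in GFP-, a log2 difference of -1.42 that stayed below 0 under both other scalings and did not pass the size rule. Among serotonin and cholinergic receptors no gene passed it as deposited, and *Htr1d* and *Chrnb4* passed it under both other scalings. The highest values were a difference of 1.97 for *Htr1d* and of 1.97 for *Chrnb4*, with *Chrnb2* and *Chrm4* at 1.57 and 1.12. *Htra2*, a mitochondrial protease that shares the prefix of the serotonin receptors, had -1.93. *Chrnb1* had -0.06 and was above 0 under both other scalings. The medians of the odorant and cholinergic receptor lists were 1.20 and 1.12, at the 93.4 and 82.0 percentiles. The serotonin receptor median, over *Htr1d* and *Htra2*, was 0.02 at the 43.5 percentile and was below 0 with both libraries rescaled to one total.

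Voltage-gated channels were represented by a few genes each. *Scn3a*, a neuronal sodium channel (chromosome 2, 65457118 to 65567492), was at 66.8 FPKM in GFP+ and 0.357 FPKM in GFP-, and was the only one of 13 sodium channel subunit genes to pass the rule as deposited (3 with a pseudocount of 0.1). *Scn8a* and *Scn3b* followed at 1.13 and 1.19 FPKM in GFP+. Of 18 calcium channel subunit genes, 6 were above 1 FPKM. All 6 had a difference above 0 and 2 passed the rule, with a median of 1.56 at the 99.2 percentile. Most of the 6 were below 1 FPKM in GFP- and passed the filter only through GFP+, which fixes the sign of their difference. *Cacna1h*, a low-threshold calcium channel, was at 32.7 against 0.229 FPKM, and the auxiliary subunit *Cacna2d1* at 8.42 against 0.0815 FPKM. *Cacna1a*, the pore of the P/Q-type channel (chromosome 8, 84415364 to 84640249), was at 3.33 against 0.182 FPKM. Its ratio was 18.2, but its log2 difference of 1.87 missed the rule with a pseudocount of 1. The gene passed the rule at 2.27 with the median ratio set to 0 and at 2.83 with one total. *Cacnb2* had 1.24. Potassium channel genes moved in both directions. Of 19 above 1 FPKM, 7 were at least 4-fold higher (3 with a pseudocount of 5, 11 with 0.1) and 2 lower. *Kcnh6* was at 75.0 against 1.12 FPKM, *Kcnab3* at 87.4 against 1.52 FPKM and *Kcnj5* at 19.8 against 0.123 FPKM. The epithelial channel subunits *Kcne3* and *Kcnn4* were at 19.6 against 154 FPKM and at 26.1 against 151 FPKM, and *Kcnn4* did not pass the rule under either other scaling. Of the mechanosensitive channels no gene passed the rule as deposited. *Tmem63c* had a difference of 1.68, which passed it under both other scalings, and *Tmem63b* one of 0.81, *Piezo1* had -0.53, and *Tmem63a* had -0.38, which turned above 0 under both other scalings. The potassium, sodium and mechanosensitive channel medians were 1.10, 1.05 and 0.21, at the 99.8, 76.7 and 59.3 percentiles.

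**Figure D2:**
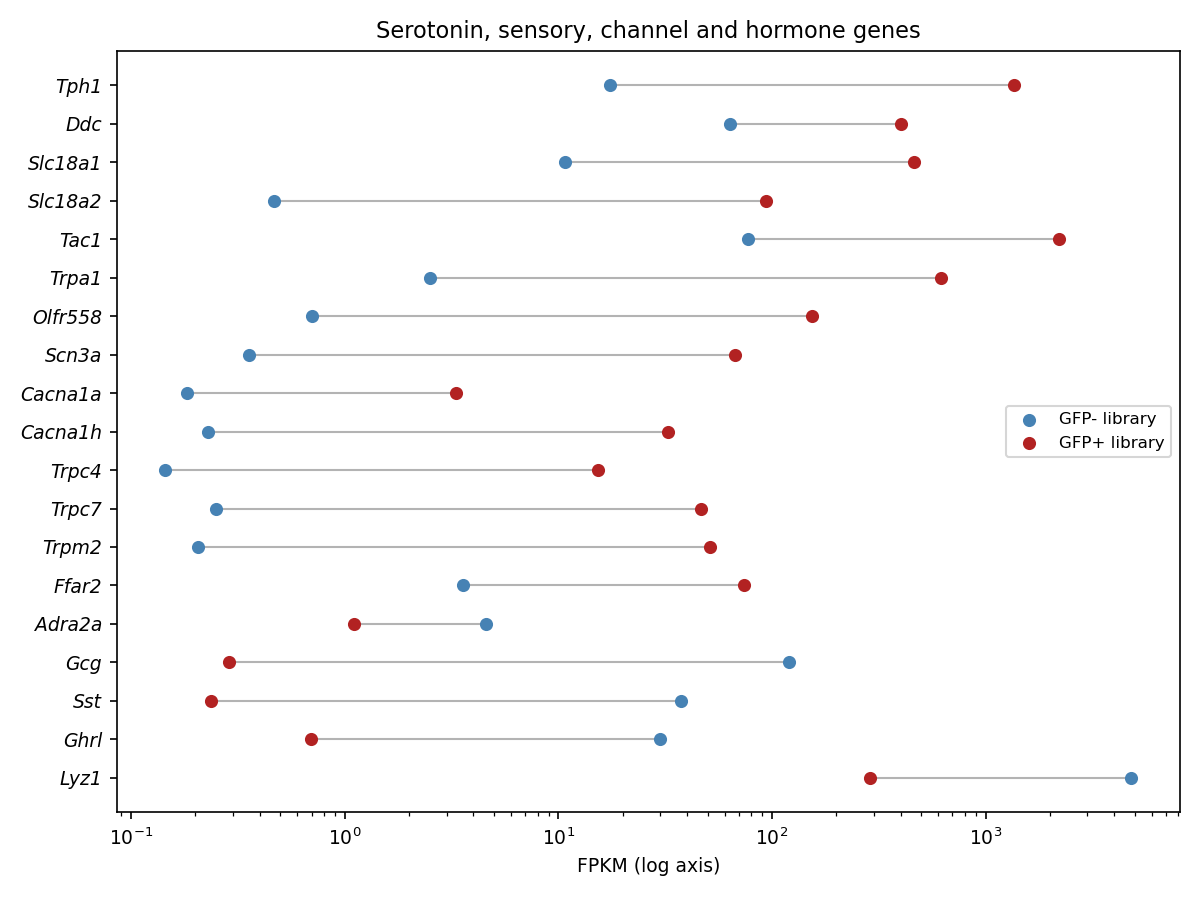
FPKM (log axis) of 19 serotonin, sensory, channel, hormone and Paneth cell genes in the GFP- library (blue) and the GFP+ library (red); each point is 1 library and the line joins the 2 values of a gene. *Trpa1* runs from 2.52 to 617 FPKM, while *Adra2a*, *Gcg*, *Sst*, *Ghrl* and *Lyz1* are lower in GFP+.

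The gut hormone genes split. Of 13 above 1 FPKM, 6 were at least 4-fold higher in GFP+ and 4 were at least 4-fold lower. *Tac1*, the substance P precursor made by enterochromaffin cells (chromosome 6, 7555071 to 7562973), was at 2200 FPKM in GFP+ and 77.5 FPKM in GFP-. *Ucn3* (urocortin) was at 509 against 3.13 FPKM, *Iapp* at 54.7 against 2.55 FPKM, *Sct* (secretin) at 94.8 against 18.5 FPKM, *Gast* at 13.0 against 0.639 FPKM and *Penk* at 8.14 against 0.137 FPKM. *Gcg*, the glucagon-like peptide gene of L cells, was at 0.286 against 120 FPKM. *Sst*, of D cells, was at 0.236 against 37.6 FPKM, *Ghrl* (ghrelin) at 0.696 against 30.0 FPKM and *Nts* at 0.0689 against 6.62 FPKM. *Cck*, *Gip* and *Pyy* lay between the thresholds, with differences of -1.52, -0.96 and -0.51. The list median was -0.51 with an interval from -4.19 to 3.97, at the 18.6 percentile (77.1 with random lists matched on length too), and was 0.67 over members of at least 5 FPKM.

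Of 21 transcription factors of the enteroendocrine lineage above 1 FPKM, 11 were at least 4-fold higher and none was 4-fold lower. Their median was 2.17 (interval 0.60 to 3.95), above each random list. With a pseudocount of 5, 7 were higher with a median of 1.40, and with 0.1, 13 were higher. *Lmx1a* was at 311 FPKM in GFP+ and 2.65 FPKM in GFP-, *Rfx6* at 120 against 2.30 FPKM, *Nkx2-2* at 179 against 4.38 FPKM and *Neurod1* at 247 against 6.51 FPKM. *Neurog3*, which marks the endocrine progenitor, had a difference of -1.43 (5.53 against 16.6 FPKM), and *Isl1* one of -0.39. Of 12 Notch pathway genes, *Dll4* was higher at 30.1 against 6.03 FPKM. *Hes1* was lower at 23.6 against 146 FPKM, as was *Lfng* at 2.34 against 13.8 FPKM. With both libraries rescaled to one total neither passed the rule, nor did *Lfng* with the median ratio set to 0. *Hey1* was at 2.62 against 0.0730 FPKM and passed the rule under both other scalings. The Notch median was 0.09, at the 53.3 percentile.

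Markers of the other epithelial lineages were also compared. All 14 Paneth cell genes above 1 FPKM were at least 4-fold lower, with a median of -4.07 (interval -4.24 to -3.73), below each random list. The defensin genes *Defa21* and *Defa22* were at 6.79 and 4.71 FPKM in GFP+ and at 179 and 107 FPKM in GFP-, and *Mptx2* was at 2.84 against 67.1 FPKM. Defensin genes are near-identical copies, so their single values are uncertain. *Lyz1* was still at 289 FPKM in GFP+, against 4819 FPKM in GFP-. Of 10 goblet cell genes, 3 were lower (6 with a pseudocount of 0.1, 2 with 5) and none higher, with a median of -1.91 below each random list. *Spink4* was at 139 against 1535 FPKM, *Agr2* at 39.0 against 282 FPKM and *Ccl9* at 1.01 against 11.7 FPKM, *Atoh1* had -1.99, and *Muc2* and *Tff3* had 0.35 and -0.22, the latter above 0 under both other scalings. Of 8 tuft cell genes, 2 were lower, among them *Rgs13* (0.767 against 7.06 FPKM), which missed the rule with the median ratio set to 0, and the median of -1.21 lay below each random list. The tuft cell genes *Avil* and *Trpm5*, the latter also in the TRP channel list, had -1.42 and -1.23. The 19 enterocyte genes had a median of -0.87 at the 28.5 percentile, inside the central 95% of random lists, and 6 of them were above 0. *Fabp1* (470 against 2157 FPKM), *Fabp2* (62.9 against 277 FPKM) and *Ada* (3.96 against 19.6 FPKM) were at least 4-fold lower as deposited and did not pass the rule under either other scaling. *Dgat1* had -1.69, and *Sis* and *Lct* had 1.09 and 1.22.

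Of 20 cell cycle genes, 15 were at least 4-fold lower in GFP+ and none higher, with a median of -2.27 (interval -2.45 to -2.05) below each random list. With the median ratio set to 0, 5 were lower with a median of -1.80, and with one total 4 were. *Cdk1* was at 11.0 FPKM in GFP+ and 94.5 FPKM in GFP-, *Aurka* at 15.9 against 107 FPKM, *Tyms* at 5.43 against 38.8 FPKM and *Pcna* at 15.9 against 102 FPKM. *Mki67* had a difference of 0.12. Of 11 stem cell genes, *Ascl2* (8.06 against 61.8 FPKM), *Cdca7* (57.7 against 299 FPKM) and *Olfm4* (217 against 892 FPKM) were at least 4-fold lower. Of these, only *Ascl2* passed the rule under the other scalings. *Smoc2* and *Lgr5* had -1.90 and -1.26, and the list median of -1.14 was at the 3.61 percentile.

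Of 88 ribosomal protein genes found by prefix, 37 were at least 4-fold lower in GFP+ and none higher, with a median of -1.86 below each random list. With one total 3 were lower, and 9 were with the median ratio set to 0, while 1 gene was higher under each. Without the kinases and other proteins that share the prefix, 36 of 71 were lower, 70 of 71 were below 0 and the median was -2.02. *Rps2* was at 26.5 against 184 FPKM and *Rpl32* at 227 against 1399 FPKM, the latter just short of the rule with one total. Ribosomal protein genes have many processed pseudogenes, and how shared reads were counted is not known. Short transcripts in general had lower ratios. Across 11335 genes with a length, the log2 difference had a Spearman rho of 0.43 with transcript length, with medians of -1.18 for the 597 genes under 1 kb, -0.65 for the 4409 of 1 to 3 kb and 0.29 for the 6329 over 3 kb. With random lists matched on length as well, the ribosomal, Paneth and cell cycle medians still lay below each of them, and the calcium channel, potassium channel and TRP channel medians lay at the 98.1, 99.5 and 99.8 percentiles.

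Markers of non-epithelial cells were few. Of 12 mesenchymal and endothelial genes, 4 reached 1 FPKM. *Vim*, an intermediate filament of mesenchymal cells, was at 237 FPKM in GFP+ and 4.90 FPKM in GFP-, and *Pecam1* at 10.4 against 0.187 FPKM. The collagen genes *Col1a1* and *Col3a1* were at 1.56 against 0.0106 FPKM and at 1.61 against 0.00593 FPKM. As deposited 2 list members were at least 4-fold higher, and 4 were with one total. Of the 4 that reached 1 FPKM, all but *Vim* were below 1 FPKM in GFP- and passed the filter only through GFP+. That fixes the sign of their difference. Among 12 immune genes *Lyz2* passed the rule, at 6.61 against 0.858 FPKM, *Cd68* had 1.22 and *Itgam* had -0.67. Among 12 neuron and glia genes *Ret* passed it, at 6.75 against 0.268 FPKM, and *Tubb3*, *Nefl* and *Gfap* had 1.15, 1.14 and 1.00. Early response genes that are raised by tissue dissociation were higher in GFP+ in 5 of 14 cases (9 with one total, 2 with a pseudocount of 5) and lower in none, with a median of 1.59 above each random list. *Jun* was at 539 against 50.6 FPKM, *Dusp1* at 103 against 10.5 FPKM, *Nr4a1* at 14.0 against 1.69 FPKM and *Fos* at 409 against 98.9 FPKM. The medians of the mesenchymal and endothelial, immune, and neuron and glia lists were 2.32, 1.22 and 1.14, at the 99.95, 82.7 and 85.5 percentiles. No symbol of a mitochondrially encoded gene was found.

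**Figure D3:**
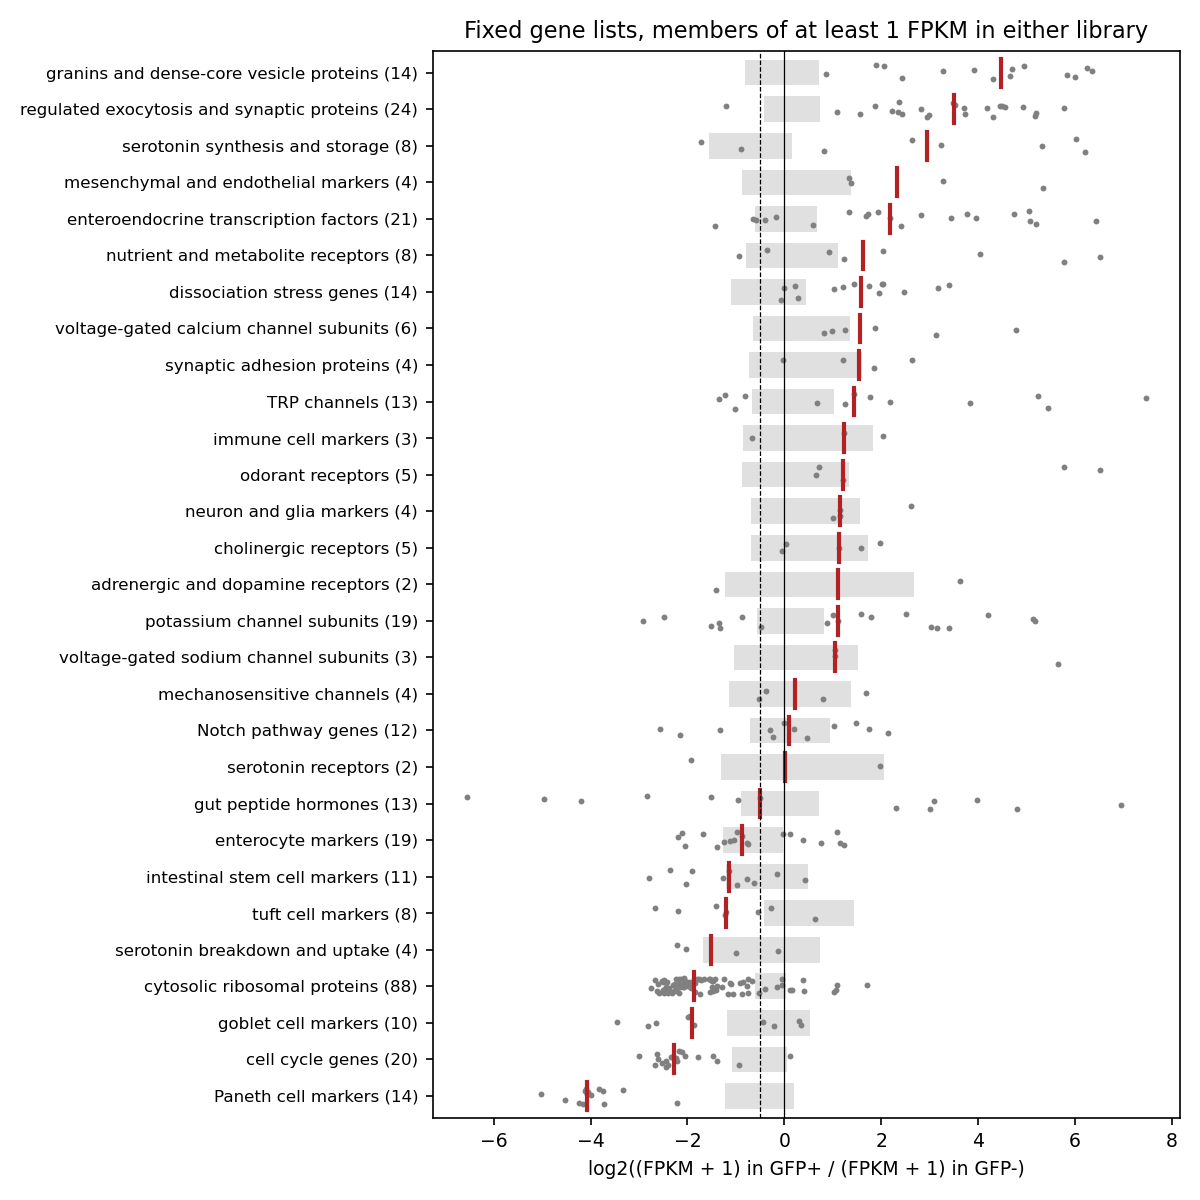
Log2 difference between the libraries (x axis, GFP+ over GFP-, pseudocount 1) for the members of each gene list of at least 1 FPKM; grey points are genes, spread vertically for visibility, red bars are list medians, grey bands span the central 95% of 10000 random list medians, and the number of members is in parentheses. The solid line is 0 and the dashed line is the median of well-expressed genes, -0.50; granin and exocytosis genes lie at the top and Paneth and cell cycle genes at the bottom.

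By the rule of largest difference, the 15 leading genes in GFP+ also held genes outside the lists. *Amigo2*, a cell adhesion protein, was at 954 FPKM against 4.28 FPKM, with the largest difference of 7.50. *Tpbg* was at 785 against 4.61 FPKM and *Gpx3*, a secreted glutathione peroxidase, at 809 against 5.44 FPKM. *Ambp* was at 241 against 1.12 FPKM, *Slc38a11*, a putative amino acid transporter, at 284 against 1.59 FPKM and *Pappa2*, a protease of insulin-like growth factor binding proteins, at 153 against 0.648 FPKM. *Fbln2*, *Acsl6*, *Pla2g7* and *Tnfrsf11b* were at 196, 259, 135 and 238 FPKM in GFP+ and at 1.14, 1.93, 0.544 and 1.81 FPKM in GFP-. The 15 genes with the smallest difference held 5 small RNA genes that were listed at 0 in GFP+ and at 457 (*Mir2137*), 67.9 (*Snord65*), 42.0 (*Snord49a*), 35.6 (*Mir1982*) and 17.7 FPKM (*Mir3968*) in GFP-. Such short features gain large FPKM from few fragments. The others included *Gcg*, *Sst*, *Ghrl*, *Defa21* and *Defa22*. The rows *AY761184*, *Gm14851* and *Gm15284* were at 7.63, 7.09 and 70.2 FPKM in GFP+ and at 367, 281 and 1659 FPKM in GFP-. The joined row of *Defa4* and *Gm10104* was at 0.103 against 35.4 FPKM.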

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

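The tests in this part were chosen after the values were seen. The status field of the files showed 5 loci without an estimate in the GFP+ library and 0 in the GFP- library, among them *Chga*, *Chgb*, *Reg4* and *Afp*. Read as values, they would put the reporter's own gene at 0 in the cells sorted for it. All 5 rows with this status were listed at 0 with both bounds at 0. Outside them, only 1 row, a small RNA gene, had at least 100 FPKM in GFP- and was listed at 0 in GFP+, so the zeros are consistent with failed estimates at loci with too many fragments. Exchanged labels are argued against by the other granin and dense-core vesicle genes, which had a median log2 difference of 4.48 with all 14 above 0. By this status the 5 loci passed the fragment limit in GFP+ and not in GFP-. The estimated scales were nearly equal, at 59.8 and 59.0 fragments per FPKM and kilobase, which points to more fragments there in GFP+. How high the 5 genes were in GFP+, and so the size of any difference between the fractions, stays open and was not tested.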

How the results depend on the processing

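The counts without small RNA genes, the matching on length, the lists without prefix sharers and the nutrient receptors without odorant receptors were chosen after seeing the data. Among the gene lists whose median lay outside the central 95% of random lists, none changed sign, and no named gene past the size rule did, under the alternatives tried. For single genes this was set in advance and is no check. No pseudocount or filter can turn the sign of a gene, and neither scaling could move a log2 difference by as much as 2. The counts moved more, from 841 higher and 545 lower genes. A pseudocount of 0.1 gave 1524 higher genes, and a pseudocount of 5 gave 353 higher and 315 lower. Rescaling to one total gave 1717 and 153, and setting the median ratio of well-expressed genes to 0 gave 1317 and 184. A 2-fold rule gave 2380 and 2743 genes, and an 8-fold rule 369 and 46. The median of the exocytosis genes was 4.71 with a pseudocount of 0.1 and 2.16 with 5. With a pseudocount of 5 the Paneth and ribosomal medians were -3.59 and -1.53. Rescaling to one total gave -3.46 for Paneth, -1.69 for cell cycle and -1.32 for ribosomal genes, and the median setting gave -3.57, -1.80 and -1.42. The higher and lower counts changed by under 1.5 times with no filter, which by construction alters neither, with a floor of 5 FPKM, single-row symbols or status OK, and without small RNA genes (813 and 537). A floor of 5 FPKM turned the hormone median from -0.51 to 0.67. Matching on length moved the breakdown and uptake list to the 1.81 percentile, the stem cell list to the 0.36 percentile and the hormone list from the 18.6 to the 77.1 percentile, inside the central 95% both times. Without odorant receptors the nutrient receptor list went from the 99.9 to the 93.5 percentile. The causes of these shifts were not tested. No replicate spread can be given. On the estimated fragment scale counting error is small at 1 FPKM for a 3 kb transcript, but not for short features. How many independent molecules the amplified fragments stand for is not known, and 5 loci have no GFP+ value.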

Other observations

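Tests on the carry-over of cells were chosen after the values were seen, and the tests on liver and blood before their results were seen. The signalling genes in this and the next paragraph were chosen singly after their values were seen, and no group of them was tested. The adenylyl cyclases *Adcy8* and *Adcy1* were at 49.5 and 5.20 FPKM in GFP+ and at 0.573 and 0.0327 FPKM in GFP-, while *Adcy6* was at 4.55 against 5.25 FPKM. The phosphodiesterases *Pde11a* and *Pde2a* were at 33.2 against 0.231 FPKM and at 58.5 against 2.05 FPKM, while *Pde9a* was at 23.7 against 24.8 FPKM. The G protein subunits *Gnao1*, *Gnaz* and *Gng4* were at 31.4, 30.6 and 130 FPKM in GFP+ and at 0.322, 0.522 and 1.98 FPKM in GFP-, and *Gnas* was at 400 against 538 FPKM. The differences of *Adcy6*, *Pde9a* and *Gnas* were below 0 as deposited and above 0 under both other scalings. The regulators *Rgs2* and *Rgs7* were at 193 against 1.70 FPKM and at 34.3 against 0.410 FPKM.

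Among receptors outside the lists, *Gpr6* was at 155 against 1.97 FPKM. The somatostatin receptors *Sstr5* and *Sstr1* were at 47.9 against 1.13 FPKM and at 22.4 against 0.345 FPKM. The adenosine receptors *Adora2a* and *Adora3* were at 33.4 against 0.531 FPKM and at 32.9 against 0.330 FPKM, and *Ptger3*, a prostaglandin receptor, was at 40.1 against 0.826 FPKM. Cytokine receptor genes *Il17re*, *Il18r1* and *Il1r1* were at 120, 54.9 and 19.0 FPKM in GFP+ and at 3.03, 0.706 and 0.0703 FPKM in GFP-.

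Enteroendocrine transcripts were present in the GFP- library. For *Gcg*, *Sst*, *Ghrl* and *Nts*, GFP+ cells that escaped the sort are argued against, since the lowest GFP- to GFP+ ratio of the 4 was 43.2. The GFP- level was 0.408% of the GFP+ level for *Trpa1*, 1.29% for *Tph1* and 3.52% for *Tac1*. Carry-over of average GFP+ cells would give one ratio, and the *Tph1* ratio was 3.16 times that of *Trpa1*. This argues against such carry-over as the only source, while it may supply part of these transcripts. With 1 library per fraction the error of these ratios is not known, so noise of this size is not excluded. For *Chga* the same share would need 32572 FPKM in GFP+, where it has no estimate, so carry-over and weakly fluorescent endocrine cells cannot be told apart there. Other endocrine cell types without the reporter, as a biological source, were not tested.

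Some genes of plasma proteins, chosen after their values were seen, were higher in GFP+ and others were not. *Ambp* was at 241 FPKM, *Alb* at 88.4 FPKM, *Serpinf2* at 88.4 FPKM, *Pros1* at 98.9 FPKM and *Cpb2* at 20.1 FPKM, against 1.12, 0.478, 4.16, 2.70 and 0.0912 FPKM in GFP-. Liver RNA as the source is argued against by 22 other abundant hepatocyte genes, whose median in GFP+ was 0.0154% of the *Alb* level, with *Ahsg*, *Fga* and *Hp* listed at 0. The largest of them, *Cyp3a11* at 37.8 FPKM, was at 31.0 FPKM in GFP-, where *Cyp2e1* was at 9.63 FPKM and the other hepatocyte genes were below 1 FPKM. Expression of such genes by the sorted endocrine cells stays as a hypothesis that these data cannot test further. A beta-globin row (*Hbb-b1* and *Hbb-bs*) was at 40.9 against 0.130 FPKM. For blood as its source the median of 5 other erythrocyte rows was 0.0230% of it, below the bound set beforehand against blood. That bound was ill chosen, because the alpha-globin genes are near-identical copies whose reads may not have been counted, so blood stays open.

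*C1qa*, of the complement system, was at 66.5 FPKM in GFP+, while its partners *C1qb* and *C1qc* were at 0.969 and 0.519 FPKM. *Gapdh*, a glycolytic enzyme with many pseudogenes, was listed at only 1.47 and 2.48 FPKM in GFP+ and GFP-. *Rn45s*, *Lars2* and *Mir6236* were at 220, 82.9 and 83.1 FPKM in GFP+ and at 672, 1198 and 1408 FPKM in GFP-.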
